A study of Mus musculus with 18 samples.

How the data were processed

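Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse HBG3 embryonic stem cells (ESC), from neural progenitor cells (NPC) derived from them and from cultures labelled as glutamatergic neurons (GN). At each of these 3 stages there were 3 genotypes, namely unedited cells (WT) and cells with an edit of Dpf2 labelled E7KO or E7KI, with 2 libraries per genotype and 18 libraries in all. Groups were taken from the sample titles, which also gave the replicate number. The titles carry a further number per genotype that is the same at every stage, and the labels do not say whether it marks a clone. If it does, differences between genotypes, called effects here, cannot be told apart from differences between individual clones. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

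The deposited table holds TPM (transcripts per 1000000) for 53379 Ensembl genes, with one column per library, and each column sums to 1000000. The submitters' processing notes name STAR 2.5.4b, kallisto, featureCounts and DESeq2 with no role, and the genome build mm10. Which tool made the TPM values, which annotation and strand setting were used and how RNA was extracted are not given in the sources used here. TPM keeps no sequencing depth, so the depth per library is unknown and no counting interval can be given. All 18 columns matched the titles, and 0 columns of the table lay outside the series.

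Gene symbols, biotypes and coordinates (GRCm38, the build also called mm10) were taken from GENCODE M21, which held 53274 of the gene identifiers and lacked 105. Values of near-identical genes (Lefty1 and Lefty2, the Zscan4 family) are uncertain, because reads can be shared between copies. The strand setting is unknown, so reads of overlapping and antisense genes cannot be told apart. Genes of microRNA hairpins and other small RNAs are listed in the table although the libraries were made from polyadenylated RNA. Their values describe fragments assigned to those short genes and not mature small RNAs. A gene with 0 TPM in both libraries of a group is described as listed at 0, without a fold change against that group. The values of the other group are given per library or as mean ± SD.

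Values were analysed as log2(TPM + 1), and a log2 fold change on this scale understates the change of genes with low TPM. Genes with at least 1 TPM in at least 2 of the 18 libraries were tested, which left 19988 genes, 15055 of them protein-coding and 1096 annotated as microRNA, snoRNA or snRNA genes. A linear model with 9 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, which leaves 9 residual degrees of freedom. Moderated statistics used an intensity trend and the robust option. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. There were 9 genotype contrasts, 2 contrasts between WT stages and 4 tests of whether a genotype effect differed between consecutive stages. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, so no single value can pass 0.05 by permutation. Standard deviations (SD) of TPM are over n = 2 libraries per group throughout, and standard errors (SE) of log2 fold changes come from the model.

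A collection of 43 gene lists (cell type markers, signalling targets, complexes and general cell states) was written before the data were examined, together with the model, the filter, the threshold, the other settings to be tried and the rule for naming genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, a rotation test of whether the genes of a list move on balance in one direction. List p-values were adjusted over the lists within a contrast. Beside the calls over all genes, the number of members called when p-values were adjusted over the list alone is given. The naming rule took the 6 genes with the largest change in each direction among called genes with at least 5 TPM in the higher group and no overlap between the libraries of the groups. It passed over predicted and unnamed genes, added up to 4 members of each described list by adjusted p, and included Dpf1, Dpf2, Dpf3, Ptbp1 and Ptbp2. Because many of the genes taken by this rule were microRNA genes, the same rule was also applied to protein-coding genes, a choice made after the values were seen.

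The model was tested on simulated data for 19988 genes, in 5 simulations with 200 genes changed in ESC E7KI each. Means were averaged over the genotypes of a stage, and the spread came from the fit to all 18 libraries. Changed genes were drawn from those above 5 TPM in ESC, so the recovery applies to such genes. The model recovered 21.7% of genes changed by 0.5 on the log2 scale, 78.2% of those changed by 1 and 97.1% of those changed by 2, with 7.52% of the calls false. An unchanged simulated contrast gave at most 2 calls, and a list shifted in the simulation had a camera p of at most 4.4e-20. The simulated noise was independent between genes, so that p does not apply to lists of correlated genes.

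The other settings tried were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-of-ratios scaling and quantile normalization. Library weights, no robust option, a minimum log2 fold change of 1, a fit of only the 6 libraries of the stage (between WT stages, of the 4 WT libraries), a replicate block and the omission of each library in turn completed them. When a library is left out, the remaining library of its group is assumed to vary like the other groups. Protein-coding genes only, removal of mitochondrially encoded genes followed by rescaling to 1000000, and a fit without NPC E7KO replicate 1 were added after the data were seen. Effects of E7KO and E7KI against the same WT libraries were compared with 100 simulations of unchanged groups. In these, all 6 libraries of the stage, WT included, were redrawn around their common mean. The noise was normal with the spread of the model, independent between genes and without a floor at 0. An excess over these simulations can therefore also come from a spread unlike that noise. No group had 4 or more libraries, so no search for outlying libraries within groups and no regrouping of libraries was possible. Isoform usage of Dpf2 exon 7 was not analysed here, because the table gives one value per gene.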

Results

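The series asked what the alternative short and long isoforms of DPF2, a subunit of the BAF chromatin remodelling complex, contribute before and after stem cells become neurons. HBG3 embryonic stem cells were edited to express one isoform or the other and were profiled with WT cells at 3 stages. The genotypes are written here as labelled, E7KO and E7KI, after exon 7 of Dpf2. The labels do not state which of them gives which isoform. The 18 libraries comprised 2 per genotype and stage. TPM values keep no depth, but each library listed between 14138 and 15718 genes at 1 TPM or more. The 2 replicates of a group correlated with r between 0.962 for NPC E7KO and 0.982 for NPC E7KI across genes, which are not independent replicates. Libraries of different genotypes of a stage could correlate as highly. ESC WT and E7KO libraries had r between 0.973 and 0.978, and the ESC WT replicates had r = 0.976.

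Libraries differed in ways that accompanied genotype or replicate. Mitochondrially encoded genes took 8.41% and 8.47% of TPM in the ESC WT libraries and 6.27% in each ESC E7KI library. In GN they took 15.4% and 13.7% in WT and 20.2% and 18% in E7KI. Ribosomal protein genes took 11.2% in each ESC WT library, 13.6% and 13.4% in ESC E7KI, 6.60% and 6.85% in GN WT and 5.70% and 5.60% in GN E7KI. The replicate 1 library of E7KO lacked transcripts of 4 Y-linked genes at all 3 stages, where none exceeded 0.307 TPM. Eif2s3y lay between 34.7 and 64.1 TPM in the other 15 libraries. In E7KO replicate 2 it was 34.7 TPM in ESC, against 55.7 and 56.4 in WT. In NPC it was 35.6 TPM there, against 58.8 and 58.5 in WT. Ddx3y, Uty and Kdm5d were also below both WT libraries in that replicate in ESC and NPC. In GN, Ddx3y and Uty were above both WT libraries in it. The E7KO replicates were therefore distinguishable cell populations throughout, and these genes were chosen after their values were seen.

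The other replicate of E7KO differed in another way in NPC. In NPC E7KO replicate 2, the median of 949 protein-coding genes of chromosome 11 lay at -0.20 against the WT mean on the log2 scale, with 82.8% of them lower. In the other libraries chromosome 11 lay between -0.09 and 0.04. The value was -0.14 with median-of-ratios scaling and -0.16 with quantile normalization, and the chromosome was chosen after its values were seen.

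**Figure D1:**
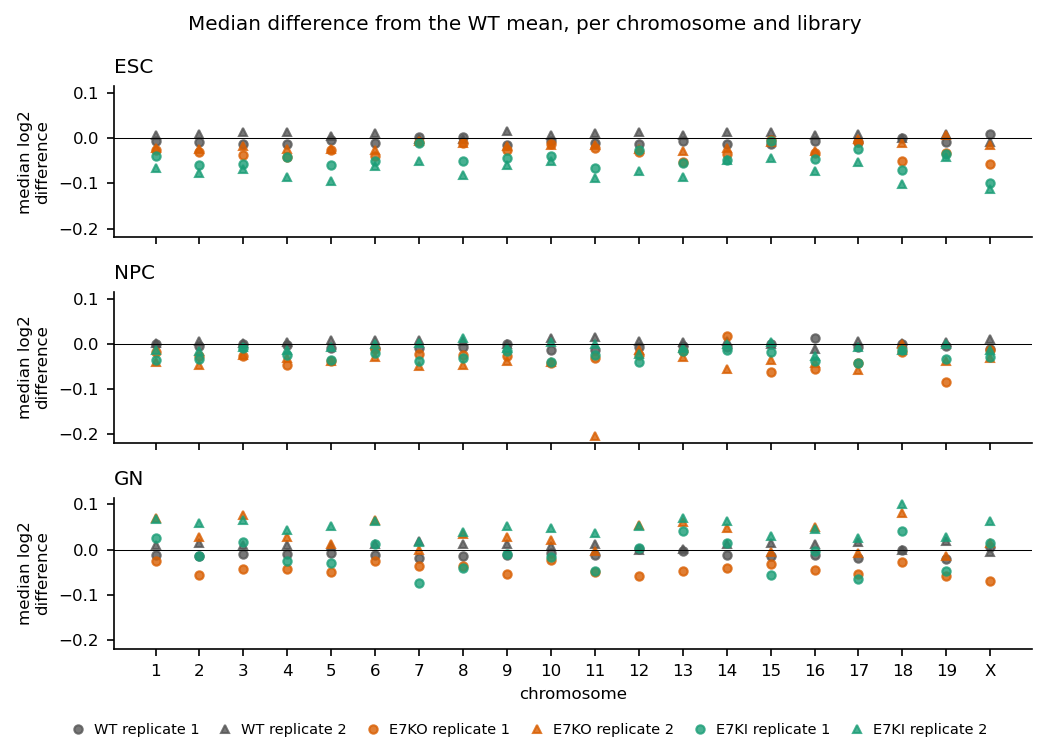
Median log2 difference from the WT mean over the protein-coding genes of each chromosome, with a point per library and a panel per stage. Chromosome 11 of NPC E7KO replicate 2 lay at -0.20, and the other autosomes of that library between -0.06 and 0.00.

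Dpf2 (ENSMUSG00000024826) lies on the minus strand of chromosome 19 (GRCm38). The alternative exon, which is exon 7 of ENSMUST00000118623.1, is 42 nt long, spans 19:5903731-5903772 and is absent from the protein-coding transcript ENSMUST00000136983.7. Gene-level TPM does not read the inclusion of that exon, so it does not check the edits. In ESC, Dpf2 was 93.5 and 106.6 TPM in WT, 89.7 and 60.3 in E7KO and 74.9 and 76.0 in E7KI. In NPC it was 79.0 and 79.7 in WT, 100 and 72.6 in E7KO and 75.3 and 79.9 in E7KI. In GN it was 45.4 and 49.3 in WT, 42.0 and 43.6 in E7KO and 31.0 and 34.9 in E7KI. Dpf2 was called in none of the 9 genotype contrasts. Its largest differences in limma were -0.51 ± 0.17 (SE) in GN E7KI against WT (adjusted p = 0.488) and -0.44 ± 0.17 in ESC E7KO against WT (adjusted p = 0.837).

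The WT libraries show the course of differentiation against which the edited cells were read. From ESC to NPC, 28 of 30 naive and general pluripotency genes fell, with a median log2 fold change of -5.88 (camera adjusted p = 1.61e-16, and adjusted p = 0.00243 with an estimated correlation). Nanog fell from 386 ± 2.59 to 0.669 ± 0.0261 TPM, and the octamer-binding factor gene Pou5f1, at 727 ± 42.9 TPM in ESC, was listed at 0 in both NPC libraries. Of 27 neural progenitor and radial glia genes, 25 rose and 1 fell (median 4.37, camera adjusted p = 3.59e-10, adjusted p = 0.103 with an estimated correlation). The Notch effector Hes5 rose from 0.291 ± 0.412 to 159 ± 20.5 TPM, and Fabp7, listed at 0 in both ESC libraries, reached 4720.1 ± 473 TPM. All 13 tested Hox genes of paralog groups 1 to 5 rose, among them Hoxb5 to 21 ± 1.39 TPM (list median 3.63, camera adjusted p = 3.23e-08, adjusted p = 0.103 with an estimated correlation). Markers of other cell types rose in NPC as well, with 11 of 11 astrocyte genes (median 4.27) and 16 of 22 mesenchyme genes (median 1.96) higher. Counts adjusted over the list alone were 28 lower for pluripotency, 26 higher for progenitors, 13 for Hox genes, 11 for astrocytes and 16 for mesenchyme. The camera calls of astrocytes (8.51e-06) and mesenchyme (0.000447) had adjusted p = 0.215 and adjusted p = 0.469 with an estimated correlation. In limma 13404 of 19988 genes were called, 6587 higher and 6817 lower in NPC.

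From NPC to GN, 31 of 33 pan-neuronal genes rose and 2 fell (median 4.56, camera adjusted p = 8.23e-13, adjusted p = 0.258 with an estimated correlation). Stmn2, a neuronal microtubule regulator, rose from 0.681 ± 0.0874 to 1051 ± 65.7 TPM, and Snap25, a component of the synaptic fusion machinery, from 6.52 ± 0.00262 to 494 ± 25. Of 19 GABAergic and glycinergic genes, 17 rose and 1 fell (median 2.03, camera adjusted p = 2.92e-06, adjusted p = 0.0146 with an estimated correlation). The vesicular transporter of inhibitory transmitters Slc32a1 rose from 0.0107 ± 0.0151 to 129 ± 0.153 TPM and the neuropeptide gene Sst from 0.257 ± 0.364 to 516 ± 39.0. Of 24 glutamatergic genes, 12 rose and 7 fell (median 1.02, camera adjusted p = 0.116, adjusted p = 0.433 with an estimated correlation), and Slc17a6, listed at 0 in both WT NPC libraries, reached 30.2 ± 12 TPM. All 20 G2/M genes fell (median -5.76, camera adjusted p = 2.16e-11, adjusted p = 0.354 with an estimated correlation), with Mki67 at 0.0687 ± 0.0454 TPM in GN, and 25 of 27 neural progenitor genes fell (median -3.88, camera adjusted p = 3.06e-11, adjusted p = 0.11 with an estimated correlation). Counts adjusted over the list alone were 31 higher for pan-neuronal and 17 higher for inhibitory genes, with 20 lower for G2/M and 25 lower for progenitors. In limma 12589 genes were called, 6065 higher and 6524 lower in GN.

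The splicing regulators and the paralogs of Dpf2 changed with stage in WT. Ptbp1, a repressor of neuronal exons, fell by 1.45 ± 0.24 on the log2 scale from ESC (417 ± 25 TPM) to NPC and by 2.63 ± 0.24 from NPC to GN (23.8 ± 4.42 TPM; limma adjusted p = 0.000167 and 1.02e-06). Ptbp2 rose by 2.34 ± 0.12 from ESC to NPC, where it reached 89.2 ± 8.43 TPM. Dpf2 fell by 0.73 ± 0.17 from NPC to GN (limma adjusted p = 0.0024), while Dpf1, the neuronal member of the family, rose by 1.86 ± 0.30 to 85.8 ± 12.6 TPM. Dpf3 was 2.70 ± 1.33 TPM in ESC, 30.2 ± 5.90 in NPC and 3.09 ± 0.305 in GN.

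**Figure D2:**
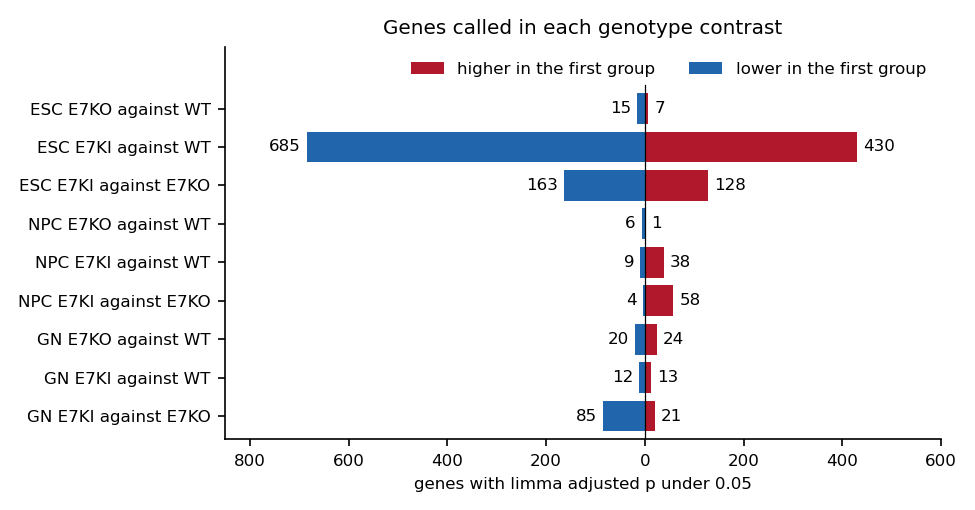
Number of genes called by limma at an adjusted p under 0.05 in each of the 9 genotype contrasts, with genes higher in the first-named group drawn to the right and lower genes to the left. ESC E7KI against WT had 430 higher and 685 lower genes, and no other contrast had more than 163 in a direction; with median-of-ratios scaling the split of that contrast was 605 higher and 468 lower.

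Among the genes lower in ESC E7KI than in WT were Nodal and 2 of its antagonists. The secreted Nodal antagonists Lefty2 (ENSMUSG00000066652) and Lefty1 (ENSMUSG00000038793) fell by 1.72 ± 0.19 and 1.71 ± 0.21 on the log2 scale, to 14 ± 1.66 and 24.8 ± 4.18 TPM from 50.3 ± 18.7 and 85.8 ± 32.0 (limma adjusted p = 0.00114 and 0.00201). Nodal (ENSMUSG00000037171) fell by 0.94 ± 0.13, from 35.6 ± 4 to 18 ± 0.627 TPM (adjusted p = 0.00382 in limma), and the SMAD corepressor gene Skil by 0.55 ± 0.10. Of 17 BMP and TGF-beta targets, 5 were lower and none higher over all genes and 7 were lower adjusted over the list alone (median -0.45, camera adjusted p = 0.000384, adjusted p = 0.213 with an estimated correlation).

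Some pluripotency genes fell in ESC E7KI. Of 14 formative and primed pluripotency genes, 4 were lower over all genes, 6 lower adjusted over the list alone, and none lay above 0 (median -0.54, camera adjusted p = 5.48e-05, adjusted p = 0.453 with an estimated correlation). They included the de novo DNA methyltransferase genes Dnmt3a (32.8 ± 0.512 against 61.3 ± 16.6 TPM) and Dnmt3b (29.0 ± 2.51 against 55.6 ± 13.6), the transcription factor gene Tcf15 (7.13 ± 1.03 against 18.5 ± 4.10) and the cadherin gene Cdh2. Of 30 naive and general pluripotency genes, 4 were lower (median -0.27, camera adjusted p = 0.0358, adjusted p = 0.453 with an estimated correlation), and adjusted over the list alone 3 were higher and 8 lower. The 4 were Dppa2 (33.7 ± 2.46 against 72.0 ± 9.22 TPM), Nr0b1 (18.8 ± 1.10 against 35.7 ± 8.58), the Nodal co-receptor gene Tdgf1 (679 ± 7.28 against 1208 ± 125) and Lin28a. The naive list was no longer called without ESC WT replicate 1 (adjusted p = 0.223), without ESC E7KI replicate 2 (0.0831), or with a pseudocount of 0.1, a 5 TPM filter, other scalings or a fit of the 6 ESC libraries alone (camera adjusted p of 0.0655 to 0.584). The formative list kept its call, with a mean of -0.56 that became -0.37 without ESC WT replicate 1.

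Genes of the two-cell-like state, a transient condition of a few cells in stem cell cultures, were lower in ESC E7KI. Of 13 members, 8 were lower over all genes and 10 adjusted over the list alone (median -0.91, camera adjusted p = 4.28e-08, adjusted p = 0.453 with an estimated correlation). Zscan4f was 8.36 ± 1.45 TPM against 26.3 ± 2.92 in WT, Zscan4c 4.38 ± 0.361 against 10.1 ± 0.211 and Zscan4d 0.615 ± 0.222 against 3.37 ± 0.273, values that are uncertain within this family. Of 33 pan-neuronal genes, 5 were lower over all genes and 6 adjusted over the list alone (median -0.16, camera adjusted p = 0.0358, adjusted p = 0.864 with an estimated correlation). Among them the neurofilament genes Nefh and Ina fell by 1.55 ± 0.16 and 1.56 ± 0.30, to 7.06 ± 0.370 and 2.23 ± 0.140 TPM. Ina ranged from -2.16 to -0.95 over the omissions of a library and was called in 1 of 4. That list was not called without ESC WT replicate 2 (camera adjusted p = 0.0654), without ESC E7KI replicate 2 (0.0621), with a pseudocount of 5 (0.149) or with a 5 TPM filter (0.0733). Smarcb1, a core subunit of the BAF complex, was 39.9 ± 0.147 TPM in E7KI and 58.5 ± 4.94 in WT (log2 fold change -0.54 ± 0.08, limma adjusted p = 0.00461) and was the only 1 of 28 BAF subunits called, with 3 adjusted over the list alone. Single developmental regulators, Mnx1 (6.63 ± 0.474 against 16.5 ± 2.89 TPM) and Hand1 (27.5 ± 3.27 against 52.6 ± 6.05), were lower in E7KI, although the motor neuron, mesoderm and trophoblast lists that hold them were not called.

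The named protein-coding genes with the largest rises in ESC E7KI were members of none of the lists. Myl3, a ventricular myosin light chain, was 40.4 ± 0.727 TPM against 6.68 ± 4.01 in WT (2.53 ± 0.41, limma adjusted p = 0.00681). The scaffold gene Pdzk1 was 41.5 ± 1.14 against 11.8 ± 1.15 (1.74 ± 0.22, adjusted p = 0.00206 in limma), Dner 8.45 ± 1.06 against 1.94 ± 0.679, and Adssl1, a muscle enzyme of purine metabolism, 21.2 ± 1.76 against 5.68 ± 3.44. The muscle list was not called (camera adjusted p = 0.187), and Myl3 and Adssl1 were each called in 1 of 4 omissions of a library. Of 12 Notch targets, 2 were higher over all genes and 3 adjusted over the list alone (median 0.29, camera adjusted p = 0.0113, adjusted p = 0.772 with an estimated correlation). The 2 were the ligand gene Dll1 (26.7 ± 2.27 against 10.9 ± 0.192 TPM) and Dtx1. The stress factor gene Ddit3 rose from 38.8 ± 13.6 to 98.4 ± 3.87 TPM (1.36 ± 0.19, adjusted p = 0.00345 in limma) and Chac1 by 0.72 ± 0.16, the 2 of 18 integrated stress response genes higher over all genes, with 5 adjusted over the list alone (median 0.15, camera adjusted p = 0.0358, adjusted p = 0.772 with an estimated correlation). The stress response list was not called without ESC WT replicate 2 (adjusted p = 0.19), without ESC E7KI replicate 2 (0.103) or with a pseudocount of 0.1 (0.0648). Among 18 p53 targets only Bbc3, which encodes a cell death activator, was higher over all genes (58.0 ± 0.525 against 37.6 ± 1.38 TPM).

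Ribosomal and mitochondrial transcripts moved in opposite directions in ESC E7KI. Of 77 ribosomal protein genes, 17 were higher over all genes, and adjusted over the list alone 47 were higher and 2 lower (median 0.23, camera adjusted p = 3.01e-23, adjusted p = 0.453 with an estimated correlation), with Rpl18a at 3447 ± 1.22 against 2546 ± 35.6 TPM. The mean of the list was 0.22, or 0.13 with quantile normalization. Of 13 mitochondrially encoded genes, 7 were lower over all genes and 10 adjusted over the list alone (median -0.51, camera adjusted p = 2.47e-07, adjusted p = 0.453 with an estimated correlation), with mt-Cytb at 1303 ± 61.4 against 2385 ± 460 TPM.

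**Figure D3:**
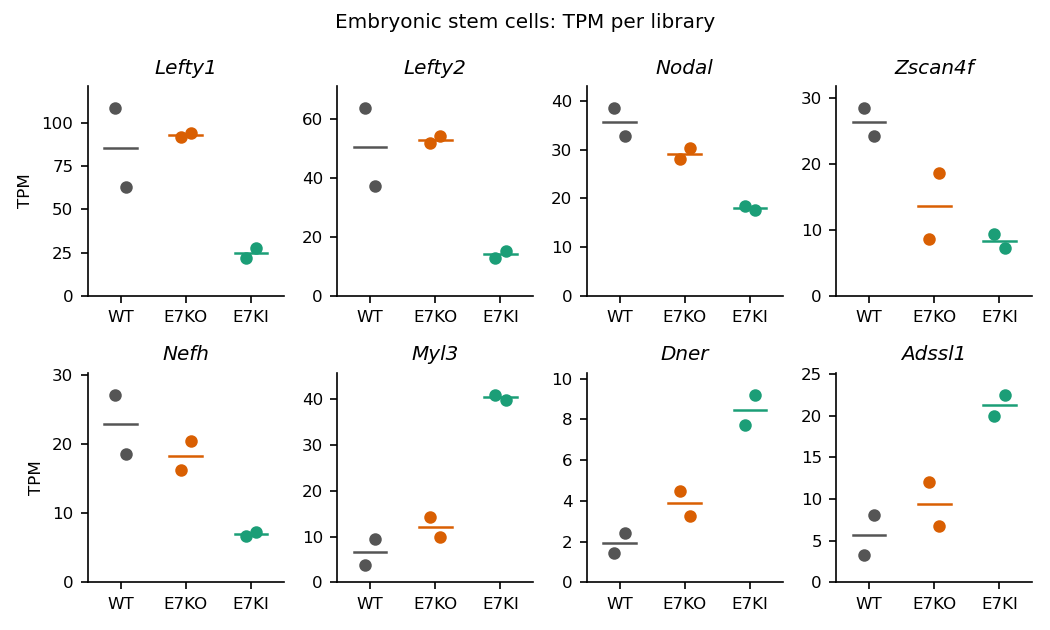
TPM of 8 genes in the 6 ESC libraries, with a point per library and a line at the mean of the 2 libraries of each genotype. Lefty1, Lefty2 and Nodal were lower in both E7KI libraries than in the WT and E7KO libraries, and Myl3, Dner and Adssl1 were higher.

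In all, limma called 1115 genes in ESC E7KI against WT, 923 of them protein-coding, and 197 changed at least 2-fold (97 higher and 100 lower). The calls were 430 higher and 685 lower, but 605 higher and 468 lower with median-of-ratios scaling and 567 higher and 594 lower with quantile normalization, so the majority direction depended on scaling. The count fell to 144 without ESC WT replicate 1, 206 without ESC E7KI replicate 1 and 227 without ESC E7KI replicate 2, and to 45 in a fit of the 6 ESC libraries alone. Of 54 named called genes, those omissions kept 10, 15 and 17, and the omission of ESC WT replicate 2 kept 41. In all 4 omissions, 8 stayed called, namely Ddit3, Lefty1, Lefty2, Nefh, Nodal, Pdzk1, Rpl18a and Zscan4d. A further 39 calls were small RNA genes (microRNA, snoRNA, snRNA and further classes such as rRNA and mitochondrial tRNA). Mir697 was listed at 0 in both WT libraries and at 12.7 and 11.99 TPM in E7KI. Mir1936 was listed at 0 in both E7KI and both E7KO libraries, against 15.9 and 10.1 TPM in WT.

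ESC E7KO cells differed from WT in few genes. The two-cell-like list was lower, with no member called over all genes, 12 of 13 lower adjusted over the list alone and none above 0 (median -0.69, camera adjusted p = 6.92e-20, adjusted p = 0.216 with an estimated correlation). Zscan4c was 3.49 and 6.89 TPM in the E7KO libraries and 9.92 and 10.2 in WT, and Zscan4f 8.61 and 18.6 against 28.4 and 24.3, so that the E7KO libraries also differed from each other. The list mean was -0.70, or -0.37 without ESC E7KO replicate 1. Nodal was 29.2 ± 1.56 TPM and not called. In limma 22 genes were called, 7 higher and 15 lower, of which 13 were small RNA genes of the same classes. An unadjusted p under 0.05 in limma was found for 1000 genes (5%). The 2 protein-coding calls, named after their values were seen, were the predicted genes Gm5039 (3.91 ± 0.517 against 7.69 ± 1.27 TPM) and Gm11237. Without ESC E7KO replicate 2, 96 genes were called, and without ESC WT replicate 2, 41. Ribosomal protein genes (median 0.08, camera adjusted p = 1.97e-12), muscle genes (0.17, 0.0201) and surface ectoderm genes (0.20, 0.00665) had no member called over all genes, and each had an adjusted p of at least 0.216 with an estimated correlation. The muscle list was called in none of the 4 omissions, surface ectoderm was lost without ESC WT replicate 1 (adjusted p = 0.331 in camera), without ESC E7KO replicate 1 (0.742) or with a pseudocount of 0.1 (0.152), and ribosomal genes without ESC E7KO replicate 1 (0.0641) or with quantile normalization (0.102).

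The direct comparison of ESC E7KI with E7KO shared part of its lower genes with the comparison against WT. Lefty1 and Lefty2 were 93.3 ± 1.62 and 52.9 ± 1.75 TPM in E7KO, above E7KI by 1.88 ± 0.21 and 1.85 ± 0.19 on the log2 scale (limma adjusted p = 0.00157 and 0.000945). Fgf17 (4.40 ± 0.0689 against 12.3 ± 0.418 TPM), Nefh (7.06 ± 0.370 against 18.4 ± 3.01) and Smarcb1 (39.9 ± 0.147 against 61.7 ± 1.36) were lower in E7KI, as were Nodal, Skil, Nr0b1, Mnx1 and Gad1. Of 17 BMP and TGF-beta targets, 4 were lower over all genes and 5 adjusted over the list alone (median -0.34, camera adjusted p = 0.00118, adjusted p = 0.239 with an estimated correlation, 0.0574 with a pseudocount of 0.1), and of 14 formative genes 1 and 8 (median -0.58, camera adjusted p = 1e-06, adjusted p = 0.239 with an estimated correlation). Higher in E7KI were Lrrc31 (9.52 ± 0.730 against 3.14 ± 0.645 TPM), Meiob, a meiotic recombination gene (11 ± 1.04 against 4.74 ± 0.363), the kallikrein gene Klk1, Ablim2 and Ddit3 (98.4 ± 3.87 against 47.6 ± 7.99). Myl3, Pdzk1, Dner and Adssl1, which were higher in E7KI than in WT, were not called here. In limma 291 genes were called, 128 higher and 163 lower in E7KI, or 180 higher and 148 lower with median-of-ratios scaling. The count was 70 without ESC E7KO replicate 2, 48 without ESC E7KI replicate 1, 83 without ESC E7KI replicate 2 and 75 in a fit of the 6 ESC libraries alone, and of 29 named genes only Lefty1, Lefty2, Lrrc31, Meiob and Smarcb1 stayed called in all 4 omissions.

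The E7KO and E7KI effects in ESC share the WT libraries, which alone makes them correlate. Across genes their log2 fold changes correlated with r = 0.456, against 0.498 in simulations with no effect, and their covariance was 0.0759 against a simulated 0.0575, a difference of 0.0183. Both contrasts called 11 genes, 10 of them in the same direction, against a mean of 0.40 and a maximum of 3 in the simulations. Only Gm5039 and Gm11237 among them were protein-coding. Several others, such as Mir199a-1 and Mir6351, were listed at 0 in both edited groups. The simulations had no floor at 0 and do not reproduce such values. At an unadjusted p under 0.05, 485 genes went the same way in both and 12 opposite ways, against simulated means of 155.4 and 3.60 and against 110.4 and 96.3 for independent lists. The controls were not split, because each part would keep only 1 of the 2 WT libraries, and some of the excess may come from the shared controls.

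In NPC, E7KI cells had more transcript of mesenchymal matrix genes than WT. All 22 mesenchyme and fibroblast genes lay above 0, with 3 higher over all genes and 18 adjusted over the list alone (median 1.07, camera adjusted p = 4.71e-35, adjusted p = 0.12 with an estimated correlation). Periostin (Postn, ENSMUSG00000027750) was 234 ± 3.61 TPM against 71.2 ± 25.8 in WT (1.75 ± 0.25, limma adjusted p = 0.0215), and the collagen-binding proteoglycan genes Lum and Dcn were 23.1 ± 2.75 against 9.11 ± 0.457 (1.25 ± 0.13, adjusted p = 0.00156 in limma) and 118 ± 3.01 against 36.2 ± 13.9. The WT libraries themselves differed in this list, with a mean of 3.55 in replicate 1 and 4.21 in replicate 2 on the log2(TPM + 1) scale, against 4.88 and 4.99 in E7KI. Other genes higher in E7KI were the calcium-binding protein gene S100a6 (30.7 ± 5.99 against 7.57 ± 1.5 TPM), the opioid peptide precursor gene Penk (21.7 ± 7.42 against 4.65 ± 1.03), the clusterin gene Clu, Fibin, the retinaldehyde reductase gene Dhrs3 (45.8 ± 5.07 against 15.3 ± 3) and the glutamate receptor gene Gria1. The potassium channel gene Kcnj16 was lower (6.12 ± 0.478 against 12.4 ± 0.306 TPM). Neural progenitor genes had a median of -0.11 with no member called (camera adjusted p = 0.2).

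In limma 47 genes were called in NPC E7KI against WT, 38 higher and 9 lower, and 36 were protein-coding. The count was 20 without NPC WT replicate 1, 80 without NPC WT replicate 2, 25 without NPC E7KI replicate 1 and 15 without NPC E7KI replicate 2. Of 10 named called genes these omissions kept 2, 8, 3 and 1, and only Lum was called in all of them.

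NPC E7KO against WT gave 7 calls in limma, 1 higher and 6 lower, and 1050 genes had an unadjusted p under 0.05. The single protein-coding call, named after its value was seen, was Tmem151a (0.219 ± 0.109 against 1.08 ± 0.0259 TPM, log2 fold change -0.77 ± 0.11, limma adjusted p = 0.0409). Mir6241 was listed at 0 in both E7KO and both E7KI libraries, and at 4.63 and 9.06 TPM in WT. Cell cycle lists were lower in camera, namely G2/M (20 genes, median -0.59, adjusted p = 1.18e-10, adjusted p = 0.877 with an estimated correlation) and G1/S (20 genes, median -0.60, adjusted p = 3.02e-05, adjusted p = 0.979 with an estimated correlation), with no member called over all genes or over the list alone. This came from E7KO replicate 1: its G2/M mean was -1.17 against WT, and that of replicate 2 was 0.0154. Mcm2, a replication licensing gene, was 23.7 and 76.2 TPM in the E7KO libraries and 71.3 and 64.5 in WT. G1/S genes also lost their call without NPC WT replicate 1 (camera adjusted p = 0.0522) and in a fit of the 6 NPC libraries alone (0.0908). Mitochondrially encoded genes made up 19% of the TPM in NPC E7KO replicate 1 and 17.5% in replicate 2, against 15% and 16.2% in WT and 17.2% and 16% in E7KI. Their list was higher in E7KO than in WT with no member called over all genes or over the list alone (median 0.23, camera adjusted p = 2.64e-08, adjusted p = 0.615 with an estimated correlation). It was called in all 4 omissions of a library, but not with quantile normalization (camera adjusted p = 0.172) or in the fit of the 6 NPC libraries alone (0.115). Lists of p53 targets, glycolysis, pan-neuronal and immediate early genes lost their call or turned without the same E7KO library, and each had an adjusted p of at least 0.877 in camera with an estimated correlation. Without NPC WT replicate 1 the p53 (0.195), glycolysis (0.0629) and pan-neuronal (0.243) calls were lost too, and without NPC WT replicate 2 the immediate early call (0.663). Leaving out NPC E7KO replicate 2 gave 1717 calls, NPC E7KO replicate 1 17, NPC WT replicate 1 14 and NPC WT replicate 2 13.

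Between NPC E7KI and E7KO the mesenchymal genes differed in the same direction, with all 22 above 0, 2 higher over all genes and 21 adjusted over the list alone (median 1.10, camera adjusted p = 4.82e-24, adjusted p = 0.354 with an estimated correlation). S100a6 (30.7 ± 5.99 against 7.34 ± 1.55 TPM), Postn (234 ± 3.61 against 73.7 ± 3), Dhrs3 (45.8 ± 5.07 against 13.8 ± 0.793), the iron exporter gene Slc40a1 (5.09 ± 0.142 against 1.05 ± 0.406), the forkhead gene Foxs1, the Notch effector gene Heyl and the hedgehog effector gene Gli1 were higher in E7KI. Lum was higher by 1.11 ± 0.13 (limma adjusted p = 0.00631) and Kcnj16 fell by 0.92 ± 0.16. In limma 62 genes were called, 58 higher and 4 lower, or 35 and 8 with quantile normalization. Leaving out NPC E7KO replicate 2 gave 2256 calls, NPC E7KO replicate 1 97, NPC E7KI replicate 1 19 and NPC E7KI replicate 2 4, and none of the 12 named called genes was called in all 4 omissions. G2/M (median 0.50) and G1/S (0.56) lists were higher in camera (adjusted p = 2.8e-06 and 0.000948), with adjusted p = 0.608 and adjusted p = 0.8 with an estimated correlation. Their means were -0.10 and -0.34 without NPC E7KO replicate 1, and the G1/S call was lost in a fit of the 6 NPC libraries alone (camera adjusted p = 0.0841). The mitochondrially encoded list was lower (median -0.17, camera adjusted p = 0.000481, adjusted p = 0.608 with an estimated correlation) with no member called. Its mean of -0.16 became -0.09 without NPC E7KO replicate 1, and the call was lost without NPC E7KI replicate 2 (camera adjusted p = 0.071), with quantile normalization (0.459) or in the fit of the 6 NPC libraries alone (0.193).

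Against the shared NPC WT libraries, the E7KO and E7KI effects had a covariance of 0.0542, below the simulated 0.0578 (difference -0.00351), and r = 0.407 against a simulated 0.498. Both contrasts called 6 genes, all in the same direction and none annotated as protein-coding, against a simulated mean of 0.34 and maximum of 3. At an unadjusted p under 0.05, 147 genes went the same way and 19 opposite ways, against simulated means of 296.2 and 7.52 and against 21.9 and 30.4 for independent lists. The simulated same-direction count exceeded the observed one, so the simulated spread did not match these libraries. An excess over such simulations in ESC or GN therefore does not by itself show a common effect.

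Genes lower in GN E7KO than in WT included some that encode neuropeptides, which were not tested as a list. Adcyap1 (ENSMUSG00000024256), which encodes PACAP, was 3.44 ± 0.826 TPM against 10.1 ± 1.45 (-1.32 ± 0.15, limma adjusted p = 0.00391), the tachykinin precursor gene Tac1 57.2 ± 3.80 against 149 ± 50.4 (-1.32 ± 0.21, adjusted p = 0.0358 in limma) and the corticotropin-releasing hormone gene Crh 2.71 ± 1.1 against 8.84 ± 2.61. The neuropeptide genes Vip (0.750 ± 0.0895 against 3.64 ± 0.0304 TPM) and Nms (1.29 ± 0.742 against 4.19 ± 0.171) were lower as well; they were chosen after their values were seen. So were the neuropeptide genes Sst, Npy and Penk, which were not called (limma adjusted p of 1, 0.794 and 0.659). The vesicular protein gene Lamp5 fell by 0.67 ± 0.10. Of 9 genes of motor and other neuron types none was called over all genes and 4 were lower adjusted over the list alone (median -0.33, camera adjusted p = 0.00033, adjusted p = 0.0711 with an estimated correlation, 0.093 with a 5 TPM filter). Of 33 pan-neuronal genes none was called over all genes and 1 was lower adjusted over the list alone (median -0.13, camera adjusted p = 0.00916, adjusted p = 0.948 with an estimated correlation), a call lost without GN WT replicate 1 (0.0788) or GN E7KO replicate 1 (0.166).

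Stress response genes were higher in GN E7KO. All 18 integrated stress response genes lay above 0, with 2 higher over all genes and 8 adjusted over the list alone (median 0.43, camera adjusted p = 8.29e-12, adjusted p = 0.0711 with an estimated correlation). The 2 were Phgdh, of serine synthesis (59.9 ± 0.374 against 35.2 ± 1.41 TPM, limma adjusted p = 0.0128), and the secreted glycoprotein gene Stc2 (22.3 ± 0.975 against 11.7 ± 0.958). All 18 p53 targets lay above 0, with 0 called over all genes and 7 higher adjusted over the list alone (median 0.41, camera adjusted p = 4.43e-08, adjusted p = 0.728 with an estimated correlation). The cytochrome oxidase subunit gene Cox6a2 (33.4 ± 4.79 against 13.6 ± 1.32 TPM), the metallothionein gene Mt1 (576 ± 48.7 against 278 ± 2.75), Sox2 (4.58 ± 0.544 against 1.86 ± 0.337), the connexin gene Gja1 (5 ± 0.183 against 2.38 ± 0.192) and Dlx5 (1.79 ± 0.357 against 0.596 ± 0.108) rose. Of 11 astrocyte genes 1 was higher over all genes and 1 adjusted over the list alone (median 0.23, camera adjusted p = 0.00887, adjusted p = 0.911 with an estimated correlation), a call lost without GN WT replicate 2 (0.0593), GN E7KO replicate 2 (0.134) or with a pseudocount of 5 (0.136). Of 27 neural progenitor genes none was called over all genes and 3 were higher adjusted over the list alone (median 0.14, camera adjusted p = 0.00197, adjusted p = 0.728 with an estimated correlation), a call lost without GN WT replicate 1 (0.0842), and its mean of 0.19 became 0.12 without GN E7KO replicate 2. Of 77 ribosomal protein genes, 1 was higher over all genes and 15 adjusted over the list alone (median 0.14, camera adjusted p = 1.26e-16, adjusted p = 0.728 with an estimated correlation), with a mean of 0.15 that became 0.082 without GN E7KO replicate 1. In limma 44 genes were called, 24 higher and 20 lower, of which 23 were protein-coding. The count was 18 without GN WT replicate 1, 23 without GN WT replicate 2 and 123 without GN E7KO replicate 1. GN E7KO replicate 2 stood apart from the other 5 GN libraries, at 46.5 on the first principal component of the stage (25% of the variance) where the others lay between -27.7 and 6.25. The E7KO replicates had the lowest r of a replicate pair in GN, 0.975 against 0.98 in WT and 0.982 in E7KI. The stress response and p53 target lists were nevertheless called in all 4 omissions of a library. Of 16 named called genes, the 3 omissions above kept 1, 3 and 8, that of GN E7KO replicate 2 kept 2, and Adcyap1 was called in all 4.

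Adcyap1, Vip and Nms were lower in GN E7KI as well, while Tac1 and Crh were not called (limma adjusted p = 0.167 and 0.581). Adcyap1 was 4.57 ± 0.509 TPM against 10.1 ± 1.45 in WT (-0.98 ± 0.15, limma adjusted p = 0.025), Vip 1.13 ± 0.189 against 3.64 ± 0.0304 and Nms 1 ± 0.360 against 4.19 ± 0.171. Trappc9, which encodes a subunit of a vesicle-tethering complex, was 7.49 ± 0.816 against 29.0 ± 8.75 TPM (-1.79 ± 0.29, adjusted p = 0.0369 in limma). Of 13 mitochondrially encoded genes 1 was higher over all genes, mt-Atp8, and 10 adjusted over the list alone, all 13 lying above 0 (median 0.51, camera adjusted p = 1.96e-15, adjusted p = 0.246 with an estimated correlation). Of 77 ribosomal protein genes none was called over all genes and 55 were lower adjusted over the list alone (median -0.26, camera adjusted p = 3.91e-50, adjusted p = 0.246 with an estimated correlation). With quantile normalization the list means went from 0.50 to 0.30 for mitochondrial and from -0.24 to -0.16 for ribosomal genes. The astrocyte list was higher with no member called over all genes or over the list alone (median 0.36, camera adjusted p = 0.00138, adjusted p = 0.528 with an estimated correlation), a call lost with a pseudocount of 5 (0.083). The immediate early list was lower (median -0.33, camera adjusted p = 1.95e-05, adjusted p = 0.425 with an estimated correlation). The chemokine gene Ccl21b and Gm10591, which had identical values, were listed at 0 in both E7KI and both E7KO libraries and at 1.27 ± 0.0784 TPM in WT. In limma 25 genes were called, 13 higher and 12 lower (18 and 11 with mitochondrially encoded genes removed), and 7 were protein-coding. None of the 3 named called genes, Adcyap1, Trappc9 and mt-Atp8, was called in all 4 omissions: without GN WT replicate 1 only 1 stayed called, and without GN WT replicate 2, GN E7KI replicate 1 or GN E7KI replicate 2 none did.

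The edited genotypes differed in GN in stress response, p53 target and ribosomal protein genes. Of 18 integrated stress response genes, 4 were lower in E7KI than in E7KO over all genes and 12 adjusted over the list alone, with none above 0 (median -0.58, camera adjusted p = 9.22e-19, adjusted p = 0.0217 with an estimated correlation). This was the only 1 of 83 list calls in genotype contrasts that was kept with an estimated correlation. Its called members were Phgdh (31.7 ± 0.792 against 59.9 ± 0.374 TPM, limma adjusted p = 0.00394), Atf3 (4.89 ± 1.23 against 10.3 ± 0.909), Trib3 (10.7 ± 2.11 against 20.2 ± 0.192) and Stc2. The mitochondrial gluconeogenic enzyme gene Pck2 (15.6 ± 2.75 against 32.3 ± 4.06 TPM), Cyb5r1 and the p53 target Bbc3 (47.4 ± 2.13 against 89.5 ± 2.79) were lower too, and Cox6a2 fell by 1.21 ± 0.15. Of 18 p53 targets 1 was lower over all genes and 4 adjusted over the list alone, with none above 0 (median -0.41, camera adjusted p = 4.92e-09, adjusted p = 0.452 with an estimated correlation). Of 77 ribosomal protein genes, 34 were lower over all genes and 67 adjusted over the list alone (median -0.42, camera adjusted p = 1.56e-80, adjusted p = 0.0646 with an estimated correlation), among them Rpl30 (807 ± 8.58 against 1154 ± 20.3 TPM) and Rps20 (156 ± 1.10 against 250.5 ± 9.03). Higher in E7KI were the neurofilament gene Nefh (49.8 ± 4.37 against 26.6 ± 0.232 TPM), 1 of 33 pan-neuronal genes called (median 0.22, camera adjusted p = 9.02e-05, adjusted p = 0.452 with an estimated correlation), and the homeobox gene Emx2 (1.96 ± 0.495 against 0.268 ± 0.0376). Camera also called other lists, among them mitochondrially encoded genes, higher in E7KI with a mean of 0.33. Mesenchyme (-0.32), surface ectoderm (-0.38) and endoderm (-0.35) genes were lower. With an estimated correlation their camera adjusted p was 0.34, 0.681, 0.452 and 0.452. GN E7KO replicate 2, which stood apart, enters this contrast. In limma 106 genes were called, 21 higher and 85 lower, and median-of-ratios scaling left 48. The count was 49 without GN E7KO replicate 1, 40 without GN E7KI replicate 1, 17 without GN E7KI replicate 2 and 19 in a fit of the 6 GN libraries alone. Of 19 named called genes, Phgdh and Rpl30 were called in all 4 omissions.

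**Figure D4:**
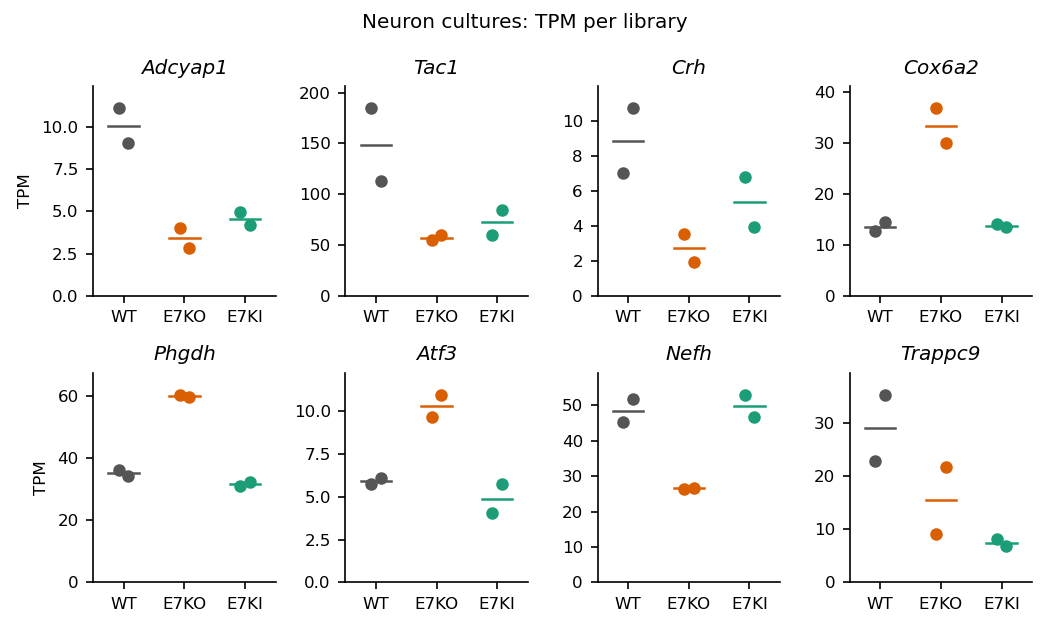
TPM of 8 genes in the 6 GN libraries, with a point per library and a line at the mean of the 2 libraries of each genotype. Adcyap1 and Tac1 were highest in the WT libraries, Cox6a2, Phgdh and Atf3 were highest in the E7KO libraries, and Trappc9 was lowest in the E7KI libraries.

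Against the shared GN WT libraries, the covariance of the E7KO and E7KI effects was 0.0703 against a simulated 0.0582, a difference of 0.0122, with r = 0.489 against 0.5004. Both contrasts called 12 genes, all in the same direction, against a simulated mean of 0.15 and maximum of 2. They included Vip, Adcyap1 and Nms, each lower in both. Ccl21b and Gm10591 had identical values, as had Gm24220 and Gm26488, so the 12 calls were not all separate. At an unadjusted p under 0.05, 414 genes went the same way and 55 opposite ways, against simulated means of 166.7 and 2.57 and against 63.0 and 63.4 for independent lists. As in ESC, part of the excess may come from the shared controls.

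**Figure D5:**
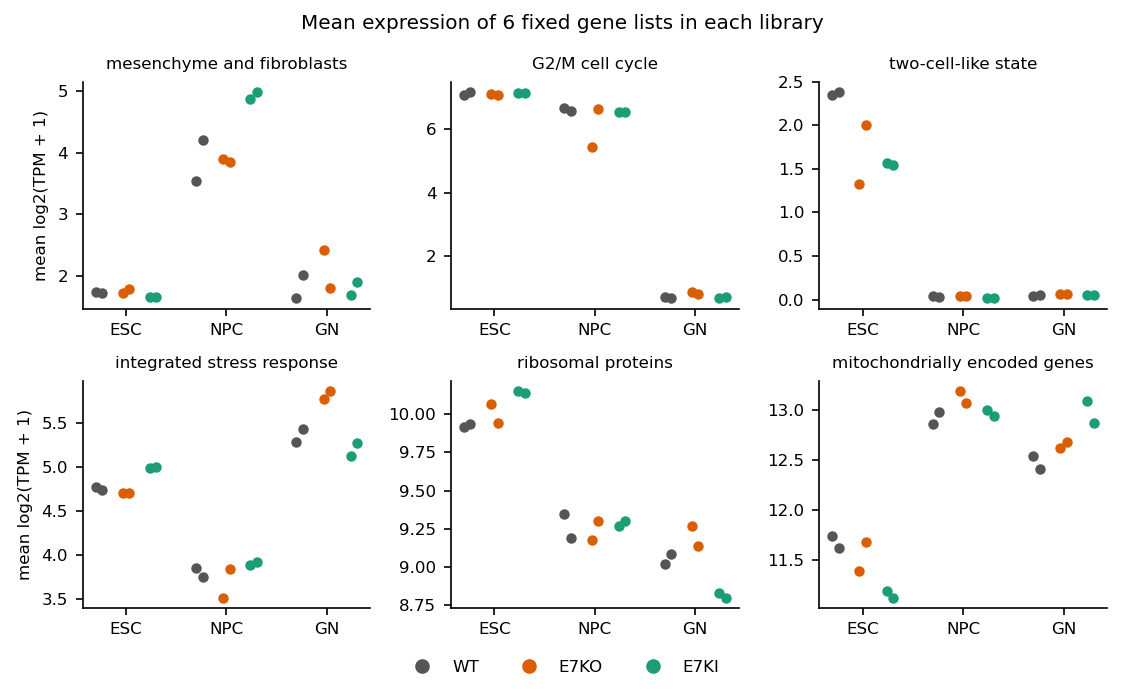
Mean log2(TPM + 1) over the members of 6 gene lists in each of the 18 libraries, grouped by stage and coloured by genotype. The mesenchyme list was 4.88 and 4.99 in the NPC E7KI libraries and at most 4.21 in the other NPC libraries, and the G2/M list was lowest among NPC libraries in E7KO replicate 1.

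Few calls were shared between stages. E7KI against WT had 1115 calls in ESC, 47 in NPC and 25 in GN, so a small overlap does not show that effects were specific to a stage. Limma called 2 genes for E7KI against WT in both ESC and NPC, 4 in both ESC and GN and 2 in both NPC and GN. Independent lists would share 2.62, 1.39 and 0.0588. The direction was the same for 1 of the 2 genes shared by ESC and NPC. It was the same for none of the 2 shared by NPC and GN and none of the 4 shared by ESC and GN. Among the 4 was mt-Atp8, lower in ESC (12534 ± 22.5 against 18264 ± 508 TPM) and higher in GN (25284 ± 1308 against 16979 ± 648). For E7KO 1 gene was shared by ESC and NPC, where independent lists would share 0.0077, and none by the other pairs of stages. The test of the difference between stages in limma called 135 genes for the E7KI effect in NPC against ESC (83 higher and 52 lower, or 51 and 54 with median-of-ratios scaling) and 27 in GN against NPC. The corresponding counts for E7KO were 17 and 11.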

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

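The comparisons of the E7KI effect between consecutive stages were planned, while the comparison of gene lists between GN and ESC and all but 2 of the tests below were chosen after the result was seen. The 2 written before were the search for neuronal RNA in NPC E7KO replicate 1 and the transcript length trend of ribosomal protein genes.

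The effect of E7KI on some genes differed between ESC and NPC. In limma, the effect in NPC minus that in ESC was 1.69 for Lefty2 (adjusted p = 0.0212), 1.03 for Nodal (adjusted p = 0.0387), 1.56 for Nefh (adjusted p = 0.0119), 1.77 for Cd34 (adjusted p = 0.041), where the effect was -1.11 in ESC and 0.66 in NPC, and -1.83 for Dner (adjusted p = 0.0396). It was also 0.97 for mt-Cytb, 0.75 for mt-Nd4l and -0.43 for Rpl18a. Lefty2 and Nodal were hardly transcribed in NPC, where Nodal was at most 0.194 TPM, so the loss of their effect follows from their absence. For S100a6 the difference was 2.28, from an effect of 1.89 in NPC, and for Lum -1.37 in GN minus NPC, from an effect of 1.25 in NPC.

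Ribosomal and mitochondrial lists changed direction between stages. The mean E7KI effect on ribosomal protein genes was 0.22 in ESC and -0.24 in GN, a difference of -0.46 (fry adjusted p = 0.00531, and camera adjusted p = 0.198 with an estimated correlation). For mitochondrially encoded genes it was -0.53 in ESC and 0.50 in GN, a difference of 1.03 (fry adjusted p = 0.00132, and camera adjusted p = 0.189 with an estimated correlation).

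The higher mesenchymal genes in NPC E7KI could reflect cultures with more mesenchymal cells. Scaling or the mitochondrial share does not account for them, because the mean log2 fold change of the list stayed at 1.06 or more under 3 other scalings. Whether a mere lack of neural progenitors accounts for them cannot be told from the other non-neural lists, of which the highest had a mean of 0.25. The endoderm, trophoblast, endothelium and surface ectoderm lists had a median log2 fold change of 0. A cell type that is absent from the cultures would not rise with a lower share of progenitors. The WT replicates also differed, by a mean of 0.66, with 95.5% of the members differing in one direction between them. A mesenchymal content that varies between cultures could give this. The E7KO replicates, however, differed by a mean of only -0.048, and the E7KI libraries lay close together. An effect of the edit remains possible. In 21 of 22 members both E7KI libraries were higher than both WT libraries, but the members moved together between the WT replicates. A varying mesenchymal content could give the same count, so the count cannot tell these explanations apart.

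NPC E7KO replicate 1 stood apart with lower cell cycle genes. The E7KO genotype alone does not account for it, because the G2/M mean of replicate 2 was 0.0154 against WT. Mixing in RNA from GN is ruled out, because 11 neuron-specific genes had a median of 0.0444% of the neuron level where 56.5% would be needed. An exchanged label within NPC is ruled out, because the library had 0.307 TPM of the Y-linked gene Eif2s3y, which was likewise nearly absent from E7KO replicate 1 at the other stages and at least 34.7 TPM in all other libraries. A culture that had left the cell cycle more than the others, or poorer cells or RNA, could give this pattern. Neither was tested. Mitochondrially encoded genes made up 19% of the TPM in this library and 15% to 17.5% in the other NPC libraries. The mean of the pan-neuronal list lay above WT in this library and at -0.17 against WT in replicate 2.

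Ribosomal protein genes were lower in GN E7KI as a list (camera adjusted p = 3.91e-50, adjusted p = 0.246 with an estimated correlation), with none of 77 called over all genes. Scaling alone does not account for all of this, but it may account for a part. The mean log2 fold change of -0.24 became -0.16 with quantile normalization or with mitochondrially encoded genes removed, and -0.27 with median-of-ratios scaling. A trend with transcript length alone may likewise account for a part, because the mean was -0.18 after that trend was subtracted. Scaling and the length trend were not combined. The astrocyte list was higher in the same contrast (mean 0.40, camera adjusted p = 0.00138, adjusted p = 0.528 with an estimated correlation) with no member called, so a different mix of cells could give the change. Less ribosome production could too, and neither was tested.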

How the results depend on the processing

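Counts of called genes depended on the settings, and the cause was not tested. Over the genotype contrasts, named genes other than microRNA genes stayed called in 202 of 572 omissions of a library and lost their call in 370.

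In ESC E7KO against WT (22 genes called), the count was 163 with no filter, 9 with a filter of 5 TPM, 73 with only the libraries of that stage and 1 among protein-coding genes, and omissions gave 19 to 96. In ESC E7KI against WT (1115), it was 2273 with library weights, 197 at a minimum log2 fold change of 1, 45 with only the libraries of that stage and 2055 with NPC E7KO replicate 1 left out of the pooled spread, and omissions gave 144 to 1167. In ESC E7KI against E7KO (291), it was 150 with a pseudocount of 0.1, 619 with 5, 459 with no filter, 1657 with weights, 84 at the minimum fold change, 75 with only the libraries of that stage and 787 without NPC E7KO replicate 1, and omissions gave 48 to 215.

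In NPC E7KO against WT (7), the count was 26 with no filter, 2 with the 5 TPM filter, 11 with only the libraries of that stage and 0 among protein-coding genes, and omissions gave 13 to 1717. In NPC E7KI against WT (47), it was 19 and 112 with the pseudocounts of 0.1 and 5, 21 with the 5 TPM filter, 174 with weights, 14 with only the libraries of that stage, 73 among protein-coding genes and 84 without NPC E7KO replicate 1, and omissions gave 15 to 80. In NPC E7KI against E7KO (62), it was 27 and 164 with the pseudocounts, 0 with weights, 9 with only the libraries of that stage and 161 among protein-coding genes, and omissions gave 4 to 2256.

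In GN E7KO against WT (44), the count was 104 with a pseudocount of 5, 81 with no filter, 9 with the 5 TPM filter, 28 with weights, 25 at the minimum fold change, 22 with only the libraries of that stage, 27 among protein-coding genes and 104 without NPC E7KO replicate 1, and omissions gave 18 to 123. In GN E7KI against WT (25), it was 68 with no filter, 12 with the 5 TPM filter, 63 with weights and 7 among protein-coding genes, and omissions gave 19 to 36. In GN E7KI against E7KO (106), it was 210 with a pseudocount of 5, 48 with median-of-ratios scaling, 28 at the minimum fold change, 19 with only the libraries of that stage and 227 without NPC E7KO replicate 1, and omissions gave 17 to 74.

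Between WT stages, the minimum fold change left 8029 of 13404 genes in NPC against ESC and 7656 of 12589 in GN against NPC, and omissions gave 12104 to 12218 and 11349 to 11534. For the E7KO effect in NPC against ESC (17), the count was 72 with no filter, 4 with the 5 TPM filter and 0 among protein-coding genes, and omissions gave 15 to 702. For the E7KO effect in GN against NPC (11), it was 35 with no filter, 3 with the 5 TPM filter, 7 with weights and 1 among protein-coding genes, and omissions gave 13 to 923. For the E7KI effect in NPC against ESC (135), it was 83 and 332 with the pseudocounts, 219 with no filter, 85 with the 5 TPM filter, 609 with weights and 380 without NPC E7KO replicate 1, and omissions gave 36 to 278. For the E7KI effect in GN against NPC (27), it was 58 with no filter, 11 with the 5 TPM filter, 51 with weights and 4 among protein-coding genes, and omissions gave 15 to 40.

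Genes called for both E7KO and E7KI in ESC (11) were 21 with a pseudocount of 5, 80 with no filter, 4 with the 5 TPM filter, 1 among protein-coding genes and 497 at an unadjusted p under 0.05, and omissions gave 10 to 57. Of the 83 list calls in genotype contrasts, 1 was kept with an estimated correlation, and omissions gave 75 to 99.

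The camera direction of a list, which is relative to all other genes, turned mainly between the omissions of NPC E7KO replicate 1 and of replicate 2. Mean log2 fold changes of the lists are given here in that order. For E7KO against WT they were -0.17 and 0.42 for pan-neuronal, 0.29 and -1.43 for G1/S, 0.015 and -1.17 for G2/M, 0.028 and -0.65 for p53 target and 0.088 and -0.59 for glycolysis genes. For E7KI against E7KO they were 0.083 and -0.51 for pan-neuronal, -0.34 and 1.39 for G1/S, -0.10 and 1.09 for G2/M, 0.0074 and 0.69 for p53 target and -0.052 and 0.62 for glycolysis genes. Cholesterol synthesis genes were 0.38 and -0.27 in E7KO against WT, -0.085 there without NPC WT replicate 2, and -0.40 and 0.25 in E7KI against E7KO. Without GN E7KO replicate 1 and replicate 2, mesenchyme genes were -0.021 and 0.60 in GN E7KO against WT and -0.0062 and -0.63 in GN E7KI against E7KO. Germline genes in GN E7KI against WT were 0.022 without GN E7KI replicate 1, 0.00028 without GN WT replicate 1 and 0.36 without GN WT replicate 2.

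A replicate block within a stage assumes that equal replicate numbers were processed together. For comparisons between stages, the block assumes that equal numbers within a genotype share a source. With the block, the counts were 65 (ESC E7KO against WT), 445 (ESC E7KI against WT) and 130 (ESC E7KI against E7KO). They were 13 (NPC E7KI against WT), 20 (NPC E7KI against E7KO), 14 (GN E7KO against WT), 13 (GN E7KI against E7KO) and 40 (E7KI effect in NPC against ESC). Replicate deviations of different groups correlated between -0.118 and 0.0432 across genes, and the main model did not pair equal numbers. Such a correlation across all tested genes cannot exclude a shared source. In E7KO, replicate 1 lacked Y-linked transcripts at all 3 stages, so equal numbers did track a cell population there. The main tests of differences between stages do not use that pairing.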

Other observations

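These observations were made after the values were seen. The GN cultures, labelled glutamatergic, carried abundant transcripts of inhibitory neurons in WT. Gad1 was 142 ± 2.92 TPM and Npy 77.9 TPM, while the cortical glutamatergic genes Slc17a7 and Tbr1 were 0.0951 and 0.573 TPM. Slc17a6, another member of the glutamatergic list, was 30.2 ± 12 TPM, so glutamatergic transcripts were present as well. Hoxb4 was 34.0 TPM and the forebrain gene Foxg1 0.224 TPM, which may suggest a hindbrain or spinal identity. Median-of-ratios scaling did not alter the direction of any called list.

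Gfap, an astrocyte intermediate filament gene, was 7.51 TPM in GN WT, 18.2 ± 5.22 in E7KO and 20.3 ± 0.708 in E7KI.

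Peg13, an imprinted noncoding gene that lies within Trappc9, was 179 and 98.2 TPM in GN WT, 257 and 161 in E7KO and 284 and 294 in E7KI. Trappc9 was 22.8 and 35.2, 9.15 and 21.6, and 8.07 and 6.91 in the same libraries. Peg13 was not called in GN E7KI against WT (limma adjusted p = 0.268).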
